A study of Homo sapiens with 3 samples.

How the data were processed

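Gene expression was measured in HCT116 cells, an established human colon cancer cell line, with 1 whole-genome oligonucleotide array per culture. Per the labels' protocols, the cultures were transfected for 48 h with 10 nM of a control siRNA, an siRNA against nucleolin, or an siRNA against TRA2B4, and total RNA was amplified and labelled with a single dye, Cy3. Each group held 1 sample, so nothing in these data measures the spread between cultures.

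The scanner files give the intensity of every spot. Per the file headers, the intensity columns were made by Agilent Feature Extraction 11.5.1.1 with a 1-colour protocol, and the array design refers to a human genome build for which no matching annotation was used here, so no coordinates are given. The processed intensity in these deposited files is background-subtracted and detrended by the scanner software and is not scaled between arrays. The spot flags (well above background, saturated, outlier) are the scanner software's own, per the file headers. The authors also deposited a table of log2 values with 18116 rows. Of these, 18093 matched probes that were not control spots, all well above background on all 3 arrays, and 23 were control spots. Differences between its columns matched those computed here from the scanner files to within 0.00271 on the log2 scale. The table's scale (log2) and direction were therefore settled, while the value that was subtracted per probe stayed unknown. The medians of its columns were 0.0082 for the control siRNA, 0.0017 for the nucleolin siRNA and 0.0564 for the TRA2B4 siRNA.

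Each array held 62976 spots, of which 4259 were control spots and were left out, and the remaining spots represented 50599 probes. The share of probes well above background was 47.4% on the control array, 43.9% on the nucleolin siRNA array and 44.1% on the TRA2B4 siRNA array. No spot was saturated. Outlier spots (195, 307 and 277 on the 3 arrays) were dropped. The 75th percentile of the processed signal was 150 on the control array, 97.3 on the nucleolin siRNA array and 105 on the TRA2B4 siRNA array, so the control array was the brighter one. All 3 arrays lay on slide 1 and came from scan 1. With 1 array per group, no comparison with the slide as a block could be made, and precision is limited by the number of arrays.

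The log2 of the processed signal was averaged over the spots of a probe, and the array's 75th percentile over probes was subtracted. The scanner files carry no gene names. RefSeq accessions of the probes, compared without versions, were looked up in a RefSeq gene table of another assembly, GRCh38.p14, used for names alone. Of the 50599 probes, 30004 received 1 gene symbol and 20595 stayed unnamed. The named probes covered 21614 genes, 6222 of them with more than 1 probe. A gene was represented by its probe with the highest mean normalised signal over the 3 arrays. A total of 13149 genes were well above background on all 3 arrays.

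With no replicates, no p-value or standard error was computed. A fixed rule of size took the place of a test: a gene was counted as higher or lower when the 2 arrays differed at least 2-fold and its probe was well above background on at least 1 of them. Genes dim on the other array are counted by their measured difference, which can exceed the bound that the lowest detected signal gives: with signals floored there, 861 of the 1055 genes counted for the nucleolin siRNA remained. The technical noise of a spot was taken from 902 probes printed 10 times on each array. The median SD of log2 signal among those spots was 0.058 on the control array, 0.0571 on the nucleolin siRNA array and 0.0641 on the TRA2B4 siRNA array, which gives a difference between 2 single spots an SD of 0.0845. Among detected probes below the median signal the median SD was larger, 0.107, 0.105 and 0.127 on the 3 arrays, so differences of dim genes are less precise. This covers neither labelling nor culture.

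Before the data were examined, 28 gene lists, the comparisons, the processing alternatives and the rule for named genes were fixed. The named genes are the 12 highest and 12 lowest per comparison among genes with an official symbol that were well above background on both arrays, differed at least 2-fold, were at or above the median signal of detected probes on the brighter array, and had no other detected probe of opposite sign. NCL, TRA2B, TRA2A and CDKN1A are always named, and so are up to 4 members of a list with the largest differences in size. Some genes that this rule names are not reported here. For each list, the median log2 difference of the members well above background on all 3 arrays was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. The resulting percentile describes these arrays and is not a test over replicates. The lists share some genes. A median at or below the 2.5th or at or above the 97.5th percentile is called outside the range of random lists.

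Both siRNA arrays were compared with the same control array, so the correlation and overlap of their differences were set beside 200 simulations of unchanged arrays that carried the spot noise alone. The steps were tested on simulated data. In a simulated nucleolin siRNA minus control siRNA comparison over 13149 genes with spot noise alone, 100% of genes changed 2.83-fold and 0% of genes changed 1.62-fold were counted, along with 1 unchanged gene. Of 200 simulated lists of 30 unchanged genes, 4.5% fell outside the range of random lists. These outcomes follow largely from the settings, since the simulated genes varied independently with spot noise alone. They check the steps and do not show how lists of related genes, or counts, vary between cultures.

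The alternatives were scaling by the median, quantile normalisation, normexp background correction with an offset of 50 followed by quantile or 75th percentile scaling, the authors' log2 table, other filters on dim probes, outlier spots kept, the mean of a gene's probes, thresholds of 1.5-fold and 3-fold, a floor at the lowest detected signal, Spearman's rho, and means in place of medians. The files used here hold no mean pixel signal, so normexp was run on the median pixel signal instead. Scaling by the 75th percentile of detected probes and by spike-in probes were added after seeing the data, as were 19 gene families defined by their symbols and 6 further lists used in the closing section. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and, for normexp and quantile normalisation, limma 3.58.1 in R 4.3.3.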

Results

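Gene expression was profiled in 3 cultures of HCT116 colon cancer cells 48 h after transfection with 10 nM of siRNA. One culture received a control siRNA, one an siRNA against nucleolin (NCL), an abundant RNA-binding protein of the nucleolus, and one an siRNA named for TRA2B4, a transcript of the splicing factor gene TRA2B. The study asked how expression differs after silencing of either target. Each group was a single array, so no difference below has a replicate check, no test was made, and folds are those between 1 culture and another. The log2 difference of 2 single spots has a technical SD of 0.0845, and the median SD of a single spot was 0.105 to 0.127 among detected probes below the median signal against 0.0499 to 0.0555 among brighter ones.

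The targeted genes were examined first. NCL was 25.7-fold lower on the nucleolin siRNA array than on the control array (log2 difference -4.68), with 3.89% of the control signal left, and on the TRA2B4 siRNA array it was higher by 0.53 on the log2 scale. Probes for TRA2B disagreed. The brighter one differed by -0.44 between the TRA2B4 siRNA and control arrays (1.36-fold lower), whereas the dimmer one, designed to another TRA2B transcript, differed by -2.65 (6.26-fold lower, 15.98% of the control signal left). On the nucleolin siRNA array the same probes differed by -0.34 and -0.74. Where these probes lie relative to the exon special to TRA2B4 was not determined, so neither is a direct check of that transcript. TRA2A, the paralogue of TRA2B, differed by 0.12 on the nucleolin siRNA array and 0.16 on the TRA2B4 siRNA array.

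**Figure D1:**
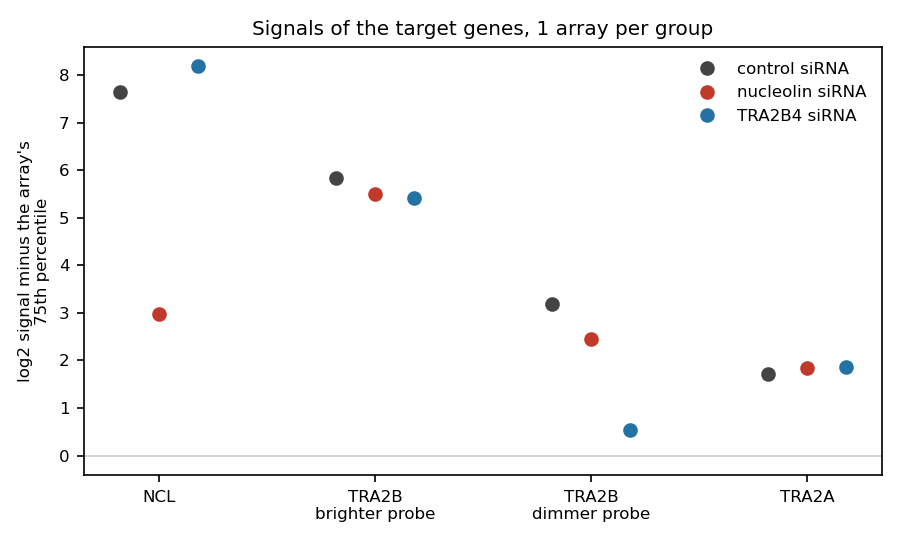
Signals of NCL, TRA2B (2 probes) and TRA2A on the 3 arrays, as log2 signal minus the array's 75th percentile, with 1 point per array. NCL differs by -4.68 between the nucleolin siRNA and control arrays, and the dimmer TRA2B probe by -2.65 between the TRA2B4 siRNA and control arrays; probes are not to be ranked against each other.

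The first comparison set the nucleolin siRNA array against the control array. Lower signals were shared by cell cycle genes and histones. Genes of DNA replication and the G1/S transition had a median log2 difference of -0.46, lower than all 10000 matched random lists, and 32 of 35 measured members were lower. CCNE2 (-1.39) and CCNE1 (-1.36), the cyclins that drive entry into S phase, CDC45 (-1.04) and GINS1 (-1.02), parts of the replicative helicase, differed most. CCNE1 (-1.32) and CDC45 (-1.05) were about as low on the TRA2B4 siRNA array. For these genes a high reading on the shared control array cannot be told apart. The helicase genes MCM2 to MCM7 differed little, from -0.16 (MCM4) to 0.25 (MCM5). G2/M and mitotic genes had a median of -0.36, again below all random lists, and 24 of 30 were lower and 6 higher, with TPX2 at -1.19, AURKB at -1.12, NUSAP1 at -0.99 and CDC25C at -0.93. Of 47 measured replication-dependent histone genes, 44 were lower and 6 at least 2-fold lower (median -0.63, below all random lists), led by H2BC7 (-1.35), H4C4 (-1.34), H4C5 (-1.19) and H2BC21 (-1.15).

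The list of CDK inhibitors and senescence markers, which mixes genes of different function, had a median of -0.34 on the nucleolin siRNA array (percentile 0.22, 13 of 17 lower). CDKN1A, which encodes the CDK inhibitor p21, was 3.58-fold lower (-1.84) on its only probe, a dim one on the nucleolin siRNA array. CDKN2D (-1.44) and CDKN2C (-1.14) were lower as well, whereas HMGA2 was higher (1.13), and the CDK inhibitor genes CDKN2B (-0.12) and CDKN1C (0.01) were near the control level. The p53 target list, which includes CDKN1A, CCNG1 (-1.23), GDF15 (-1.20) and SESN2 (-1.04), had a median of -0.15 that lay within the range of random lists (percentile 6.74). On the TRA2B4 siRNA array GDF15 (-1.31) was also lower and HMGA2 (1.17) also higher. For these genes a part from the shared control array cannot be told apart. All 8 measured mRNAs reported as ligands of nucleolin were lower or level (median -0.65, percentile 0.05), with the apoptosis inhibitor BCL2 at -1.64, APP at -1.17, BCL2L1 at -0.71 and GADD45A at -0.66. The BCL2 family list, which shares BCL2 and BCL2L1 with it, had a median of -0.36 (percentile 0.16) and included BCL2A1 at -0.94, BMF at -0.79 and BCL2L2 at -0.75.

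Lists of signalling, lysosomal and stress response genes had negative medians in the same comparison. NF-kB and inflammatory secretory genes had a median of -0.56 (percentile 0.005, 12 of 15 lower), with the protease gene PLAU at -1.61 and the chemokine genes CXCL8 at -0.89 and CXCL1 at -0.78. Between the siRNA arrays the median of this list was -0.21 (percentile 18.2), within the range of random lists. CXCL1 was lower still on the TRA2B4 siRNA array (-1.86). Immediate early genes had a median of -0.33 (percentile 0.02, 18 of 26 lower), with ETV5 at -2.29 and JUNB at -1.15, while PHLDA1 was higher (1.03). Lysosome and autophagy genes had a median of -0.31 (percentile 0.11, 23 of 29 lower), led by MAP1LC3B (-0.99), CTSB (-0.89), MCOLN1 (-0.89) and NPC2 (-0.82). The list of the unfolded protein and integrated stress response had a median of -0.21 (percentile 0.53, 20 of 31 lower and 11 higher), with DDIT3 at -1.54, CHAC1 at -1.23, CRELD2 at -1.05 and SLC3A2 at -0.98.

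Other lists had higher signals on the nucleolin siRNA array. Heat shock proteins had a median of 0.35 (percentile 99.99, 15 of 17 higher), with HSPA1B at 0.94, HSP90AB1 at 0.90, HSPH1 at 0.70 and DNAJB1 at 0.65. Cholesterol synthesis genes had a median of 0.25 (percentile 99.96), with SC5D at 1.05 and INSIG1 at 0.95, although 7 of 25 measured members were lower. Wnt targets had a median of 0.26 (percentile 98.9), led by AXIN2 (1.23), SOX4 (0.91) and RNF43 (0.86). Cytosolic ribosomal protein genes had a median of 0.17 (percentile 99.96, 66 of 78 higher), which came to -0.05 under median scaling, -0.04 under spike-in scaling and -0.03 under normexp with the 75th percentile. Median and spike-in scaling each move all genes of this comparison by the same -0.21, so a median of this size changes sign under them by construction and the list keeps its place among random lists. Genes of ribosome biogenesis and RNA polymerase I, the process in which nucleolin acts, had a median of 0.13 (percentile 99.7), which came to -0.08, -0.08 and -0.05 under the same settings. HEATR1 (1.62) and UTP20 (1.31), both needed to make the small ribosomal subunit, were higher, and UBTF, an RNA polymerase I factor, was at -0.95. MYC and its targets had a median of 0.20 (percentile 99.58), with TFRC at 0.70 and HSPD1 at 0.51, and came to -0.02 under median scaling and -0.01 under spike-in scaling, through the same shift.

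Other lists lay within the range of random lists on the nucleolin siRNA array. Medians were 0.01 for interferon response genes, 0.09 for SR proteins with TRA2 and their kinases, 0.01 for hnRNP proteins and other splicing regulators, 0.12 for glycolysis and hypoxia genes and -0.01 for oxidative phosphorylation. They were 0.19 for intestinal differentiation, -0.06 for TGF-beta response and mesenchymal genes, -0.05 for small RNA processing and Argonaute proteins and -0.03 for snoRNA host genes. Single members stood out in some, such as DICER1 (-1.29), the splicing regulators PTBP3 (-1.52) and NONO (-1.30), and SRSF6 (-1.04). Markers of other cell types, which a cell line should lack, had medians of 0.25 over 8 measured immune markers and 0.37 over 6 measured fibroblast and endothelial markers, both within the range of random lists.

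After NCL, the lowest genes were SCARNA8 (9.31-fold lower), a guide RNA of Cajal bodies, SPIN1 (9.02-fold lower), a reader of histone methylation, TMEM65 (6.27-fold lower), ETV5 (4.88-fold lower), EFCAB14 (4.85-fold lower) and ARHGAP19 (4.70-fold lower). SERPINE2 (4.47-fold lower), PTPN11 (4.38-fold lower), which encodes the phosphatase SHP2, NETO2 (4.20-fold lower), DUSP14 (4.17-fold lower) and the RAS gene NRAS (4.13-fold lower) followed. The highest were COL9A1 (19.7-fold higher), a collagen gene, UGT2B11 (9.67-fold higher), GPR20 (4.25-fold higher), the glutamate transporter gene SLC1A3 (3.54-fold higher), HEATR1 (3.08-fold higher) and the adrenergic receptor gene ADRB1 (3.06-fold higher). COL9A1 was dim on the control array (normalised log2 signal -3.61), so its fold is less precise. COL9A1 was also higher on the TRA2B4 siRNA array (log2 difference 2.12), so a low reading on the shared control array cannot be told apart. SLC1A3 was at -0.004 on the log2 scale when its probes were averaged. DESI2 (2.996-fold higher), GPER1 (2.98-fold higher), BPNT2 (2.97-fold higher), ACTL8 (2.93-fold higher) and FNDC10 (2.80-fold higher) followed. BPNT2 (log2 difference 1.56), DESI2 (1.225) and HEATR1 (1.02) were also higher on the TRA2B4 siRNA array. The limit of the shared control array given for COL9A1 applies to them as well.

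Of 14489 genes compared, 441 were at least 2-fold higher and 614 at least 2-fold lower, and of these 227 and 394 were well above background on both arrays. The split moved with the processing. It was 310 higher and 1031 lower under median scaling and 311 and 1026 under spike-in scaling, which both shift all genes by -0.21. With the scaling kept, it was 66 and 259 after normexp background correction and 146 and 335 over the probes of the authors' log2 table. The balance turned or evened out under other choices, with 1259 higher and 830 lower without a filter on dim probes, 209 and 174 at 3-fold, and 429 and 432 with signals floored.

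**Figure D2:**
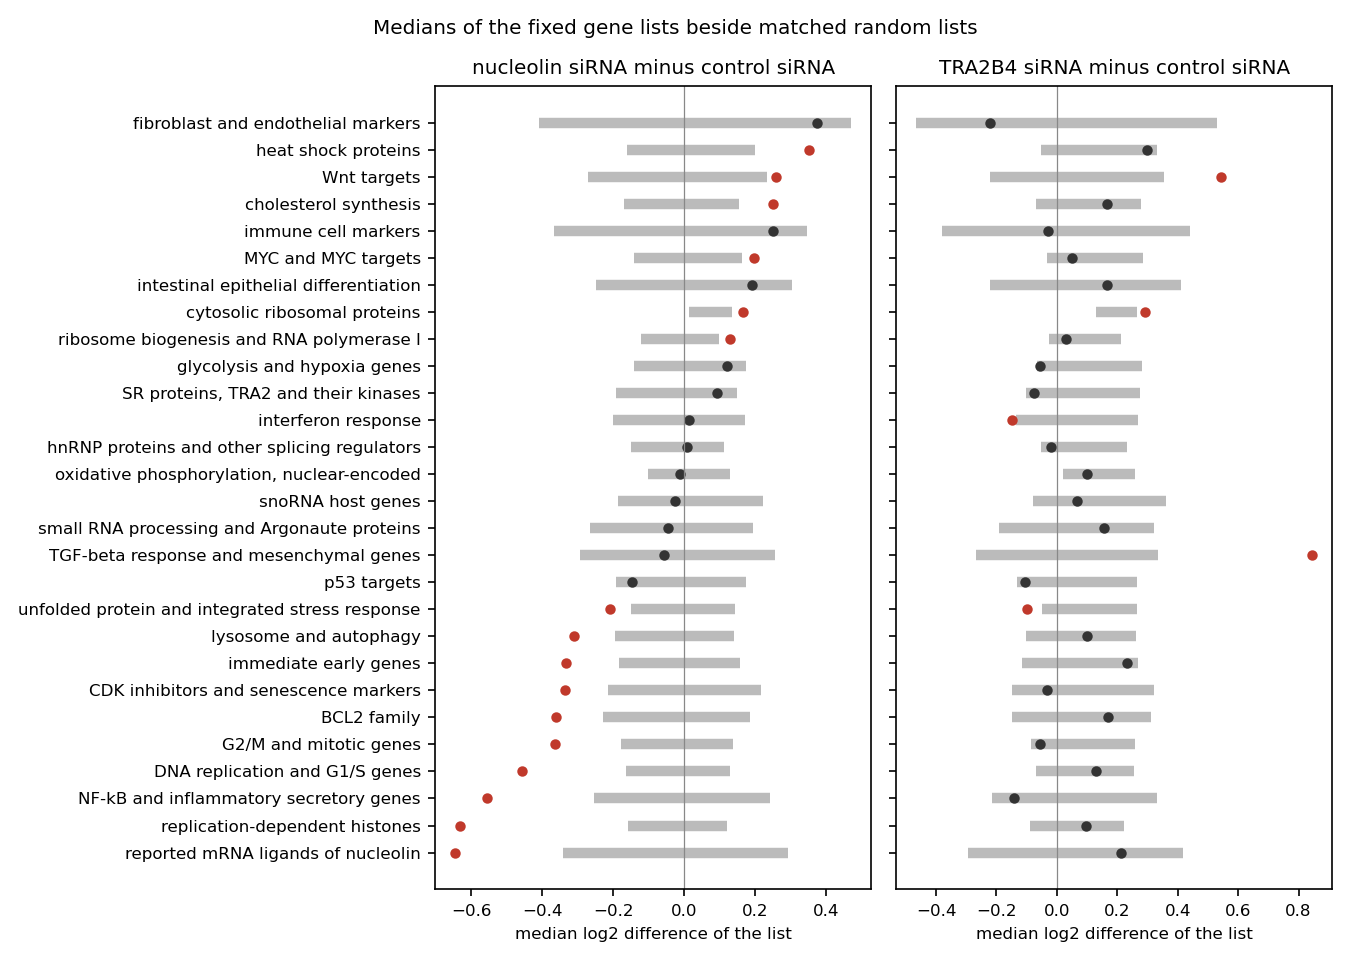
Medians of the 28 fixed gene lists (points, log2 difference) for the nucleolin siRNA array minus the control array and for the TRA2B4 siRNA array minus the control array. Grey bars span 2 SD on either side of the median of matched random lists, and red points lie outside the range of random lists by their percentile; histones and DNA replication genes lie low in the first panel (-0.63 and -0.46) and TGF-beta response genes lie high in the second (0.85).

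The second comparison set the TRA2B4 siRNA array against the control array. Its clearest group was the list of TGF-beta response and mesenchymal genes. All 14 measured members were higher, 6 of them at least 2-fold, and the median of 0.85 was above all 10000 random lists. CCN2 (2.79) and CCN1 (2.48), which encode secreted matrix-associated proteins, SNAI2 (1.58), a transcription factor of epithelial-mesenchymal transition, and the receptor gene TGFBR1 (1.42) differed most. The rise did not extend to the 3 detected fibroblast transcripts examined outside the list. TAGLN (-0.94), COL1A1 (-0.57) and ACTA2 (-0.28) were all lower. Wnt targets were higher too (median 0.54, percentile 99.97), with SP5 at 1.27, AXIN2 at 1.105, the cyclin gene CCND1 at 0.97 and TCF7 at 0.93, though 4 of 12 were lower, among them MYC (-0.53). They were also high on the nucleolin siRNA array (0.26). Between the siRNA arrays their median was 0.07 (percentile 83.0), so a part from the shared control array cannot be told apart. Fibroblast and endothelial markers had a median of -0.22 and immune markers of -0.03, within the range of random lists.

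Cytosolic ribosomal protein genes had a median of 0.29 (percentile 99.75, 74 of 78 higher), which turned to -0.02 under quantile normalisation. Their matched random lists had a median of 0.20, because bright genes in general were higher on this array. The list of the unfolded protein and integrated stress response had a median of -0.10 (percentile 0.79), with ATF5 at -1.67, DDIT4 at -1.62 and PDIA4 at -1.21, but the chaperone gene HSPA5 at 1.05. On the nucleolin siRNA array the ribosomal protein list was also high (0.17) and the unfolded protein list also low (-0.21). For both lists a part from the shared control array cannot be told apart. Interferon response genes had a median of -0.15 (percentile 2.31), which came to 0.001 without a filter on dim probes, with BST2 at -0.83, EIF2AK2 at 0.76, RIGI at -0.74 and IRF9 at -0.70.

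Cell cycle lists lay within the range of random lists on the TRA2B4 siRNA array, with members going both ways. DNA replication and G1/S genes had a median of 0.13, with E2F1 at -1.67, MCM6 at -1.33, CCNE1 at -1.32 and CDC45 at -1.05, against RRM2 at 1.01. G2/M genes had a median of -0.06. Replication-dependent histones had a median of 0.10, yet 8 of 47 were at least 2-fold higher and none that much lower, led by H2BC12 (2.03), H2BC9 (1.31), H1-2 (1.26) and H2BC14 (1.18). CDK inhibitors and senescence markers had a median of -0.03, with CDKN2B at -1.81, HMGA2 at 1.17 and CDKN1A at -0.07. The p53 target list had a median of -0.11, with AEN at -1.84 and GDF15 at -1.31 against MDM2 at 1.01.

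Of the remaining lists, none lay outside the range of random lists on the TRA2B4 siRNA array. Heat shock proteins had a median of 0.30, immediate early genes 0.23, with JUN at 1.65, the mRNAs reported as nucleolin ligands 0.21, the BCL2 family 0.17, with BMF at -1.39, and cholesterol synthesis 0.17, with STARD4 at 1.22 and CYP51A1 at 1.20. Intestinal differentiation stood at 0.17, small RNA processing at 0.16, lysosome and autophagy at 0.10, oxidative phosphorylation at 0.10, snoRNA host genes at 0.07 and MYC targets at 0.05, with POLR3G at -1.87. Ribosome biogenesis had a median of 0.03, with DDX18 at -2.44 and DDX21 at -1.21. Negative medians were found for NF-kB and inflammatory genes (-0.14, with CXCL1 at -1.86 and CXCL2 at -1.64), SR proteins with TRA2 and their kinases (-0.08), glycolysis and hypoxia (-0.06, with PGAM1 at -1.38) and hnRNP proteins and other splicing regulators (-0.02, with RBM10 at -1.16).

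FLT3LG, a haematopoietic growth factor gene, was 9.74-fold higher on the TRA2B4 siRNA array, ahead of CCN2 (6.94-fold higher), CCN1 (5.56-fold higher), the polarity gene PARD6B (5.51-fold higher), DCLK1 (5.40-fold higher), HOXC4 (4.74-fold higher), PLSCR4 (4.46-fold higher) and F2RL1 (4.43-fold higher). NEDD4 (4.14-fold higher), H2BC12 (4.08-fold higher) and PIGX (3.67-fold higher) followed. NEDD4 (log2 difference 1.32) and F2RL1 (1.17) were also higher on the nucleolin siRNA array, so a part from the shared control array cannot be told apart. Among the lowest were ZBED5-AS1 (7.06-fold lower), EPN3 (6.18-fold lower), the mitochondrial ribosomal protein gene MRPL19 (5.45-fold lower), LIMK1 (5.43-fold lower), a kinase of the actin cytoskeleton, the helicase gene DDX18 (5.42-fold lower) and U2SURP (5.39-fold lower), a U2 snRNP-associated factor. The epithelial protease gene PRSS8 (5.17-fold lower), SEPHS2 (4.90-fold lower), ATXN7L3B (4.88-fold lower), INTS14 (4.64-fold lower), ANO6 (4.49-fold lower) and TULP3 (4.39-fold lower) were the others.

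In all, 629 of 14518 genes were at least 2-fold higher and 804 at least 2-fold lower on the TRA2B4 siRNA array, of which 391 and 522 were well above background on both arrays. Under median scaling, which moved the median of all compared genes by -0.21, the split was 429 higher and 1250 lower, and after normexp background correction with the scaling kept it was 127 and 293. Without a filter on dim probes it turned to 1459 higher and 1010 lower, at 3-fold to 265 and 228, and with signals floored to 607 and 599.

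**Figure D3:**
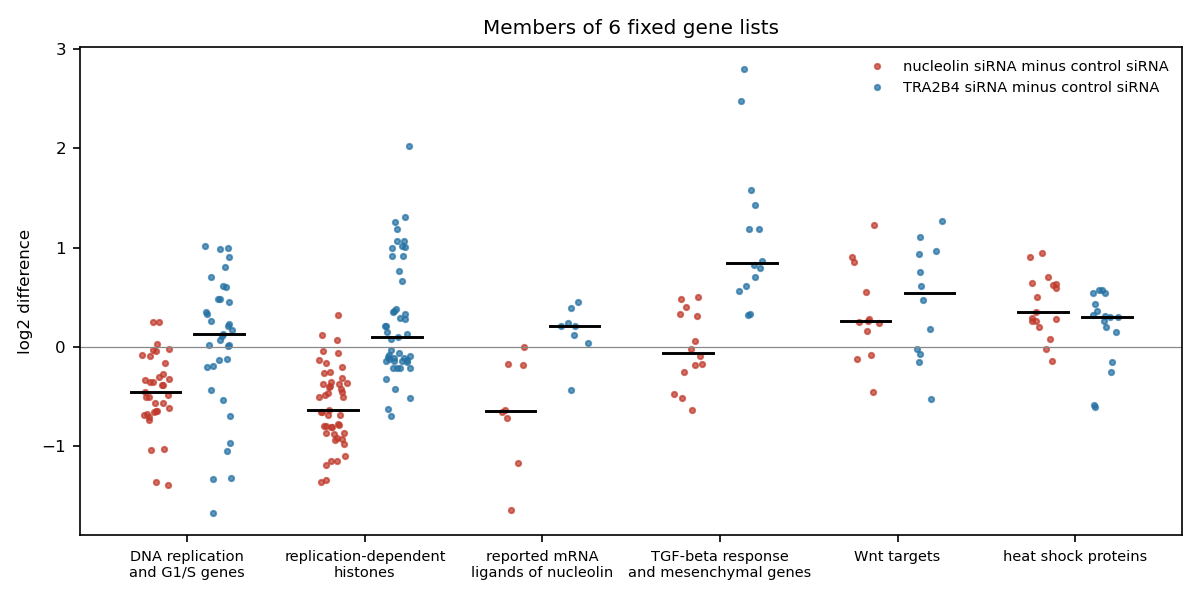
Log2 differences of the members of 6 fixed gene lists, nucleolin siRNA minus control siRNA in red and TRA2B4 siRNA minus control siRNA in blue, with 1 point per gene and a black line at the median. All 14 TGF-beta response and mesenchymal genes lie above 0 on the TRA2B4 siRNA array, and 44 of 47 replication-dependent histones lie below 0 on the nucleolin siRNA array.

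The third comparison set the nucleolin siRNA array against the TRA2B4 siRNA array. The control array entered its list results through the choice of probes and of detected members. Replication-dependent histones (median -0.75, 46 of 47 lower and 18 at least 2-fold lower) lay below all random lists, and TGF-beta response and mesenchymal genes (-0.85, percentile 0.02), immediate early genes (-0.60, percentile 0.01), DNA replication and G1/S genes (-0.48, percentile 0.03) and lysosome and autophagy genes (-0.48, percentile 0.03, 28 of 29 lower) also lay low. The mRNAs reported as nucleolin ligands (-0.71, percentile 0.4) and CDK inhibitors with senescence markers (-0.38, percentile 1.73) completed the low side. Interferon response genes (0.30, percentile 99.75) and heat shock proteins (0.19, percentile 99.5) lay high. Ribosome biogenesis genes (0.11, percentile 99.83), MYC targets (0.10, percentile 98.92) and hnRNP proteins with other splicing regulators (0.10, percentile 99.13) lay high as well. Their medians came to -0.08, -0.08 and -0.09 under spike-in scaling, which shifts all genes of this comparison by -0.18 and leaves their percentiles as they were. Other lists outside the range on the nucleolin siRNA array against the control lay within it here. G2/M genes (-0.25, percentile 7.18), NF-kB genes (-0.21, 18.2), the BCL2 family (-0.275, 9.27) and cholesterol synthesis (0.03, 93.7) were among them. So were Wnt targets (0.07, 83.0), cytosolic ribosomal proteins (-0.075, 91.2) and the unfolded protein and integrated stress response (-0.29, 2.575). A part from the shared control array cannot be told apart for them.

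GRHL2, a transcription factor of epithelial cells, was 10.3-fold higher on the nucleolin siRNA array than on the TRA2B4 siRNA array, with EPN3 (7.64-fold higher), UGT2B11 (7.10-fold higher), PRSS8 (7.05-fold higher), DDX18 (6.75-fold higher) and CFDP1 (6.72-fold higher) next. MRPL19, ZBED5-AS1, U2SURP, UBAC2-AS1 and SLC5A3 were between 5.69-fold and 6.65-fold higher. NCL was 37.1-fold lower. The guide RNAs of Cajal bodies SCARNA8 (18.6-fold lower), SCARNA4 (10.4-fold lower) and SCARNA11 (9.90-fold lower), were among the lowest, with SPIN1 (14.6-fold lower), CCN2 (9.89-fold lower), FLT3LG (9.20-fold lower), HEG1 (8.55-fold lower), CCN1 (7.70-fold lower), SLC12A4 (7.70-fold lower), SERPINE2 (6.57-fold lower) and HOXC4 (6.25-fold lower). A total of 1035 of 14174 genes were at least 2-fold higher and 1105 at least 2-fold lower. The split was 1296 higher and 885 lower when scaled to detected probes, which moved the median of all compared genes by 0.10, and 770 and 1619 under spike-in scaling, which moved it by -0.18.

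Across the 13149 genes well above background on all 3 arrays, the differences of both siRNA arrays from the control correlated weakly (Pearson r = 0.171, Spearman rho = 0.169). Genes are not independent replicates, and the comparisons share the control array. Unchanged arrays that carry spot noise alone gave a simulated r of 0.402 and a covariance of 0.0068, against an observed covariance of 0.0426. Among these genes, 47 were at least 2-fold higher on both siRNA arrays, where independent lists would share 5.21, and 35 were at least 2-fold lower on both, against 15.4. The simulated overlaps of unchanged arrays were 0.11 and 0.17 genes. Shared genes included COL9A1, HEATR1, AXIN2 and HMGA2 on the higher side and CCNE1, CDC45 and GDF15 on the lower side. In opposite directions, GRHL2 alone was higher on the nucleolin siRNA array and lower on the TRA2B4 siRNA array (7.71 for independent lists). Its difference of -2.00 on the latter array came to -0.87 under normexp with quantile normalisation and -0.81 under normexp with the 75th percentile, which ends the 2-fold call. A further 12 genes were lower on the first and higher on the second (10.4 for independent lists), among them SCARNA4, SCARNA11 and HEG1. The single control array cannot be split, so part of the excess of shared genes may come from that array.

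**Figure D4:**
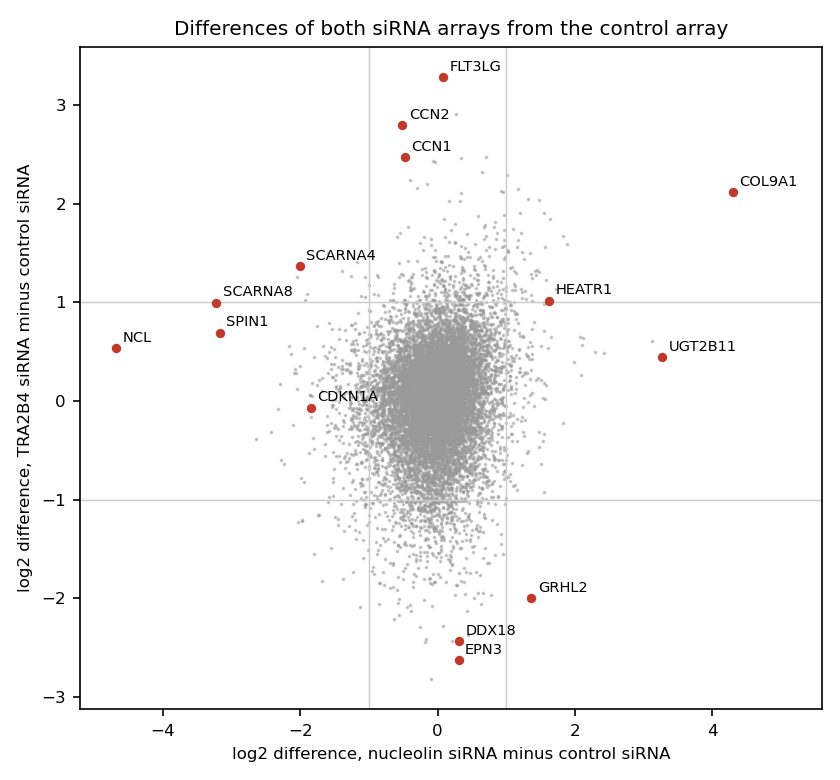
Log2 difference from the control array for each of 13149 genes, nucleolin siRNA on the horizontal axis and TRA2B4 siRNA on the vertical axis, with lines at 2-fold and 14 genes named. Most genes lie near the centre (r = 0.171). COL9A1, which is dim on the control array, is high on both siRNA arrays, and GRHL2 is higher on one and lower on the other.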

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

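The tests of S phase genes, of a low control array and of fibroblast transcripts were chosen after their results had been seen.

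Probes that carry no gene symbol here took no part in the comparisons of genes, yet a larger share of them differed from the control array. Of 5472 such probes detected on the nucleolin siRNA or the control array, 462 (8.44%) were at least 2-fold higher on the nucleolin siRNA array and 374 (6.83%) at least 2-fold lower, beside 3.04% and 4.24% of named genes. Of 5511 compared for the TRA2B4 siRNA array, 515 (9.34%) were at least 2-fold higher and 491 (8.91%) at least 2-fold lower, beside 4.33% and 5.54% of named genes. Unnamed probes were counted singly and named genes by their brightest probe.

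Replication-dependent histones (median -0.63) and the guide RNAs of Cajal bodies (scaRNAs, median -0.41, 16 of 19 lower and 6 at least 2-fold lower) were lower on the nucleolin siRNA array than on the control array. Both kinds of RNA lack a poly(A) tail, so weaker labelling of such RNA was considered. It predicts lower snoRNAs and other RNAs without a tail, but the median of 174 of them was 0.13, at percentile 99.81 of random lists, which argues against it. A smaller share of cells in S phase remains a candidate explanation for the histones, since DNA replication and G1/S genes, which are polyadenylated, lay at percentile 0, below all random lists. A loss of histone transcripts of every kind also stays open, because 11 replication-independent histones had a median of -0.32 at percentile 0.565, with 9 lower and 2 higher. These histones are not fully apart from the cell cycle genes, since CENPA also belongs to the low G2/M list. The result therefore does not separate these explanations. Neither was tested for the scaRNAs.

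TGF-beta response and mesenchymal genes were higher on the TRA2B4 siRNA array than on the control array (median 0.85). Array scaling is argued against by the lowest median over 9 settings, 0.538 under normexp with quantile normalisation. A low control array predicts a like rise on the nucleolin siRNA array, where the median was -0.058. Fibroblast RNA in the culture is argued against as well, since 0 of 8 abundant fibroblast transcripts were at least 2-fold higher: 5 were not well above background on any array, so they have no measured ratio, and the 3 detected ones, COL1A1 (-0.57), TAGLN (-0.94) and ACTA2 (-0.28), were lower. An effect of the silencing, of the siRNA on other transcripts, or of the single culture may underlie the pattern, and these cannot be separated with 1 array.

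GRHL2 (-2.00), PRSS8 (-2.37) and EPN3 (-2.63), genes of epithelial cells, were lower on the TRA2B4 siRNA array than on the control array. The size of the GRHL2 difference depends on the processing: it was -0.807 under normexp with the 75th percentile. Normexp adds an offset and was run on the median pixel signal, and these changes were not separated. EPN3 also moved, to -1.71 under normexp with quantile normalisation and -1.78 under normexp with the 75th percentile. PRSS8 and EPN3 stayed more than 2-fold lower under all 7 scaling and background settings run.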

How the results depend on the processing

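Scaling by spike-in probes and by the 75th percentile of detected probes was added after seeing the data. Each array group holds 1 sample, so replicates could not be left out and the slide could not serve as a block. No paired analysis was possible because each group holds 1 sample. Signal over background limits the lists and the correlation to the 13149 of 21614 genes that were detected on all 3 arrays. The causes of changes were not tested, except that filters, thresholds and the authors' table, which holds detected probes alone, change by construction which genes can be counted.

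Counts of genes at least 2-fold higher and lower moved by over 1.5 times as follows. For nucleolin siRNA minus control siRNA (441 and 614) they were 75 and 141 under normexp with quantile normalisation, 66 and 259 under normexp with the 75th percentile, 146 and 335 in the authors' table, 195 and 389 with detection on all 3 arrays, 93 and 275 with the brighter array above the median, 1290 and 1745 at 1.5-fold, and 209 and 174 at 3-fold. Without a filter on dim probes 1259 were higher, and 1031 were lower under median scaling and 1026 under spike-in scaling. For TRA2B4 siRNA minus control siRNA (629 and 804), in the same order of settings, they were 125 and 216, 127 and 293, 267 and 456, 351 and 520, 195 and 325, 1754 and 1936, and 265 and 228. Without a filter 1459 were higher, and under median scaling 1250 were lower. For nucleolin siRNA minus TRA2B4 siRNA (1035 and 1105) they were 384 and 311, 276 and 395, and 607 and 650 in the first 3 settings, 412 and 523 with the brighter array above the median, 2274 and 2695 at 1.5-fold, and 405 and 414 at 3-fold. The other 45 counts stayed within 1.5 times. Of the 1055 genes counted for the nucleolin siRNA, 990 were also counted under quantile normalisation and 208 under normexp with quantile normalisation.

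The correlation of both siRNA differences (0.171) was 0.277 under normexp with the 75th percentile and 0.417 without a filter on dim probes, and moved by less than 0.05 under 11 others. NCL (-4.68) came to -4.89 under median and under spike-in scaling and to -4.53 under normexp with quantile normalisation. The brighter TRA2B probe (-0.44) came to -0.65 under median scaling, -0.53 under quantile normalisation and -0.59 under normexp with the 75th percentile, and the mean of the TRA2B probes was -1.54. The dimmer probe (-2.65) came to -2.85 under median scaling, -2.25 under normexp with quantile normalisation and -2.36 under normexp with the 75th percentile. No target value changed sign under the settings run.

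Reversals were limited to lists with medians of at most 0.291 in size and to 1 named gene. Those under median and spike-in scaling follow from a shift of all genes alike, which leaves the percentiles as they were. On the nucleolin siRNA array, cytosolic ribosomal proteins turned to -0.046 under median scaling, -0.033 under normexp with the 75th percentile and -0.044 under spike-in scaling, ribosome biogenesis to -0.081, -0.052 and -0.080, and MYC targets to -0.016 under median and -0.014 under spike-in scaling. On the TRA2B4 siRNA array, ribosomal proteins turned from 0.291 to -0.018 under quantile normalisation, which moved the median of all compared genes by -0.045. Interferon genes turned to 0.001 without a filter. Between the siRNA arrays, ribosome biogenesis (-0.075), MYC targets (-0.082) and hnRNP proteins (-0.087) turned under spike-in scaling. SLC1A3 came to -0.004 as the mean of its probes. Of the other list values, 838 moved by less than 1 SD of random lists and 238 by more, and of the values of named genes 446 moved by less than the spot noise and 268 by more, with no change of sign among lists outside the range of random lists or named genes.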

Other observations

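The tests of ERK pathway output and all gene families in this part were chosen after the data had been seen.

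Among 19 gene families defined by their symbols, 4 lay outside the range of random lists for the nucleolin siRNA and 5 for the TRA2B4 siRNA, each against the control. The scaRNAs, which guide the modification of spliceosomal RNAs, went opposite ways: their median was -0.41 on the nucleolin siRNA array (percentile 0.03), with SCARNA8 at -3.22, SCARNA11 at -2.05 and SCARNA4 at -2.01, and 0.55 on the TRA2B4 siRNA array (percentile 100, 18 of 19 higher). Keratin genes (0.21, percentile 97.58) and zinc finger genes of the ZNF family (0.07 over 316 genes, percentile 99.55) lay high on the nucleolin siRNA array, as did 11 other RNAs without a poly(A) tail (0.52, percentile 99.99). On the TRA2B4 siRNA array, proteasome subunits (0.30, percentile 99.68, 28 of 36 higher) and snoRNAs (0.16, percentile 99.7, 12 of 163 at least 2-fold higher) lay high, and DEAD-box helicases (-0.15, percentile 1.07) and ZNF genes (-0.04, percentile 1.18) lay low. Small medians such as those of the ZNF genes and keratins are near or below the shift of -0.21 that median scaling gives all genes.

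SNORA75, a snoRNA encoded within an intron of NCL, was higher by 0.87 on the nucleolin siRNA array, where the mRNA of NCL differed by -4.68, and by 1.21 on the TRA2B4 siRNA array, where NCL was at 0.53. SNORA75 was dim on the control array (normalised log2 signal -2.34), so its differences are less precise. Because it was higher on both siRNA arrays, a low reading on the shared control array cannot be told apart.

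Higher YAP/TAZ target expression was tested as a hypothesis for the TRA2B4 siRNA array, because CCN1 and CCN2 are known targets. The list tested left out CCN1, CCN2, DOCK5, NT5E (1.27 on this array) and members of the TGF-beta response and mesenchymal list. Of its 13 measured targets, 10 were higher and F3 differed most among them (1.17). Their median of 0.21 lay at percentile 86.9, short of what the hypothesis predicts for targets other than those left out. Lower expression of GRHL2-dependent epithelial genes on the same array was tested because GRHL2 and PRSS8 were lower. The median of 21 such genes was 0.16 at percentile 74.5, which argues against it.

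Lower ERK pathway output was considered for the nucleolin siRNA array, where NRAS, PTPN11, ETV5 and DUSP14, genes of the RAS and ERK pathway, were each more than 4-fold lower. Of 14 other measured ERK output genes, 9 were lower and the median of -0.40 lay at percentile 0.17, but 10 of the 14 also belong to the immediate early genes already reported as low, so this mostly repeats that result. Of the 4 outside that list, EPHA2 (-1.51), CCND1 (-0.45) and SPRED2 (-0.44) were lower and SPRED1 (0.70) was higher, too few to decide. The hypothesis stays open. Effects of the nucleolin siRNA on other transcripts were not tested, because the labels give no siRNA sequences.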
